A study of Mus musculus with 3 samples.

How the data were processed

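Circular chromosome conformation capture with sequencing (4C-seq) recovers the DNA that lay close to a chosen fragment, the viewpoint, when nuclei were fixed. Per the labels' protocols, mouse embryos of embryonic day 11.5 with 44 to 45 somites were dissected, the forelimbs of 20 embryos were divided into anterior and posterior parts, and telencephalic vesicles served as a control tissue. Per the labels' protocols, dissociated cells were fixed with 2% formaldehyde for 10 min, chromatin was cut with NlaIII and ligated, and the product was cut with DpnII, ligated again and amplified by inverse PCR from the Ptch1 promoter. The labels name 3 libraries, 1 for each tissue, so that nothing measured here has a replicate, an SD or a p-value. Whether the telencephalon library holds the same number of embryos is not given in the sources used here.

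The authors deposited, for each library, a normalised 4C signal along chromosome 13 on the mm9 build, per the submitters' processing notes. The aligner, the read filters, the normalisation factor and the read totals are not given in the sources used here. Each file lists 1001 positions, 1 kb apart, from 63,199,984 to 64,199,984, and no column carries a name. For every position the deposited signal is summarised in 48 sliding windows of 2 to 49 kb, with 3 quantities per window. The meaning of the columns was read from the values: the width of a window from the empty positions at the ends of the span, and the quantities from their order. In all windows of all libraries the second quantity was at or above the first and the first at or above the third, with 0 violations. They were therefore treated as a running median, an upper quantile and a lower quantile, and the quantile levels are not given in the sources used here. No value was negative.

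Sequencing depth is unknown, because the files hold no read counts, and no counting interval was computed. A feature of the deposited signal limits what it can show. Over the 780 positions lying 10 to 400 kb from the viewpoint, the 5 kb running median took a single value at 75.6% of positions in telencephalon (0.0193), 78.6% in anterior limb (0.0264) and 75.6% in posterior limb (0.0259). With the next most frequent value (0.0245, 0.0276 and 0.0269) these shares were 91.0%, 95.0% and 93.1%. These repeated levels are called the baseline. Whether they are measured values or a fill-in level set by the authors' processing is not given in the sources used here, and a fold against a library at such a level is relative to it. They differed between libraries: the median over the analysed positions was 1.36-fold higher in anterior limb and 1.34-fold higher in posterior limb than in telencephalon (log2 0.45 and 0.43). Ratios are therefore given as deposited and, where it matters, after each profile was divided by its own median.

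The reference was the mouse NCBIM37 genome, the assembly that mm9 is made from, with the GENCODE M1 annotation. The viewpoint interval of the labels was set against this reference as a check of the build: it began and ended on NlaIII sites, with 0 NlaIII sites and 1 DpnII site inside. For each 5 kb window the NlaIII fragment ends whose first 30 bases occur once among the 211 sequences of the reference were counted. The median window held 52 ends, of which 49 were unique in this sense. The 5th percentile was 26 unique ends.

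The choices that follow were made before the data were examined. The main setting was the 5 kb running median without rescaling, with positions within 10 kb of the viewpoint left out. Signal was averaged in bins of 10 to 50, 50 to 100, 100 to 200 and 200 to 400 kb on each side, and the share of signal on the higher-coordinate side was taken from the mean per kb of both sides. A contact peak was the highest position within 10 kb on either side, with a signal at least 2 times the median of its own bin, and peaks of different tissues within 5 kb of each other counted as shared. A limb interval was a run of at least 2 kb in which both limb libraries were at least 2 times telencephalon, with the higher tissue at or above its own median and runs under 2 kb apart joined. The opposite direction, and the posterior against the anterior limb, used the same rule. The fold of an interval is that of the mean signals of the libraries nearest to each other, after adding 0.000412, the smallest value above 0. Profiles were compared by Pearson and Spearman correlation of log2 signal across positions, which overlap and are not replicates.

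The items named in the text were set by rule: at most 5 peaks in each tissue, at most 10 intervals in each direction between limb and telencephalon, at most 5 in each direction between the limb parts, the viewpoint, genes overlapping these, and listed neighbours whose start lies within the span (Fancc, Ercc6l2 and Hsd17b3). The starts of Slc35d2, Aopep, Fbp1, Fbp2 and Gas1 lie outside it. Other positions that are named were chosen after their values were seen, and this is said there.

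Alternatives were windows of 2, 10 and 20 kb, exclusion of 5 or 20 kb, profiles divided by their median or sum, a pseudocount of the 5th percentile (0.0193), folds of 1.5 and 3, no filter on level, a minimum run of 5 kb, each limb library alone, other peak rules, and bin medians. Use of the upper quantile, of the upper quantile with its own smallest value above 0 as offset (0.0234 in place of 0.000412), and of only those windows with at least 20 unique ends was added after seeing the data. With no replicates, a value counted as moved when it differed by more than 1.5 times. The interval and peak routines were tested on simulated profiles of 780 positions. Of 200 simulated limb intervals at a true fold of 1.5, 0% were recovered, and 100% were recovered at folds of 2.5 and of 4, with 0 false intervals. Both limb profiles were set to exactly this multiple of the simulated telencephalon, on a flat noisy background without repeated levels. A 2-fold rule had to give these shares, so they check the routine only. They do not measure how many intervals are missed or falsely called in the deposited profiles. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.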

Results

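Contacts of the Ptch1 promoter were measured by 4C-seq in telencephalon, anterior forelimb and posterior forelimb of mouse embryos at stage E11.5. Ptch1 encodes the receptor of Hedgehog ligands and is itself transcribed in response to them, and the design asked which stretches of DNA its promoter touches in limb cells and in a control tissue. There were 3 libraries, 1 per tissue, without replicates, so the differences below have no replicate check. The contrast between the limb parts, which are different libraries of the same organ, is given as a yardstick and not as an error. Depth was unknown, and values are the authors' normalised 4C signal in 5 kb windows.

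The viewpoint was an NlaIII fragment of 1163 bp on chromosome 13, 63,667,995 to 63,669,157 (mm9). Ptch1 (ENSMUSG00000021466.5) lies on the minus strand at 63,610,261 to 63,674,474, so that lower coordinates run along the gene body and on to Fancc, a DNA repair gene at 63,406,017 to 63,598,586. The labelled viewpoint position, 63,669,139, was 2.31 kb upstream of the first exon of the annotated transcript with 23 exons, whose exon numbers are used here, and 5.34 kb inside the most upstream annotated start. Higher coordinates run through an intergenic stretch to Ercc6l2, a helicase-family gene linked to DNA repair, at 63,916,548 to 64,001,610. Signal was highest beside the viewpoint in every library, at 63,665,984 (named after its values were seen), with 1.26 in telencephalon, 1.19 in anterior limb and 1.51 in posterior limb.

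Beyond 10 kb, raised contact lay in the body of Ptch1 in all 3 tissues. Over 10 to 50 kb on the gene-body side the mean signal was 0.0517 in telencephalon, 0.0438 in anterior limb and 0.0771 in posterior limb, which is 2.67, 1.66 and 2.97 times each library's own median. On the upstream side the same distances gave 0.0223, 0.0272 and 0.0272, close to baseline. Of the 40 positions in this bin on the gene-body side, 20 in telencephalon, 9 in anterior limb and 26 in posterior limb reached 2 times their own median, and on the upstream side 0 did in each. The upstream side held 30.2%, 38.3% and 26.1% of the signal within 50 kb, and 46.04%, 48.24% and 45.54% of that within 400 kb.

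Farther out the Fancc side fell to baseline. At 50 to 100 kb the means were 0.0233 in telencephalon, 0.0268 in anterior limb and 0.0276 in posterior limb. At 200 to 400 kb on the Fancc side anterior limb was 1.36 times telencephalon as deposited and 0.993 times after each profile was divided by its median. The offset between the medians of these profiles was itself 1.36.

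**Figure D1:**
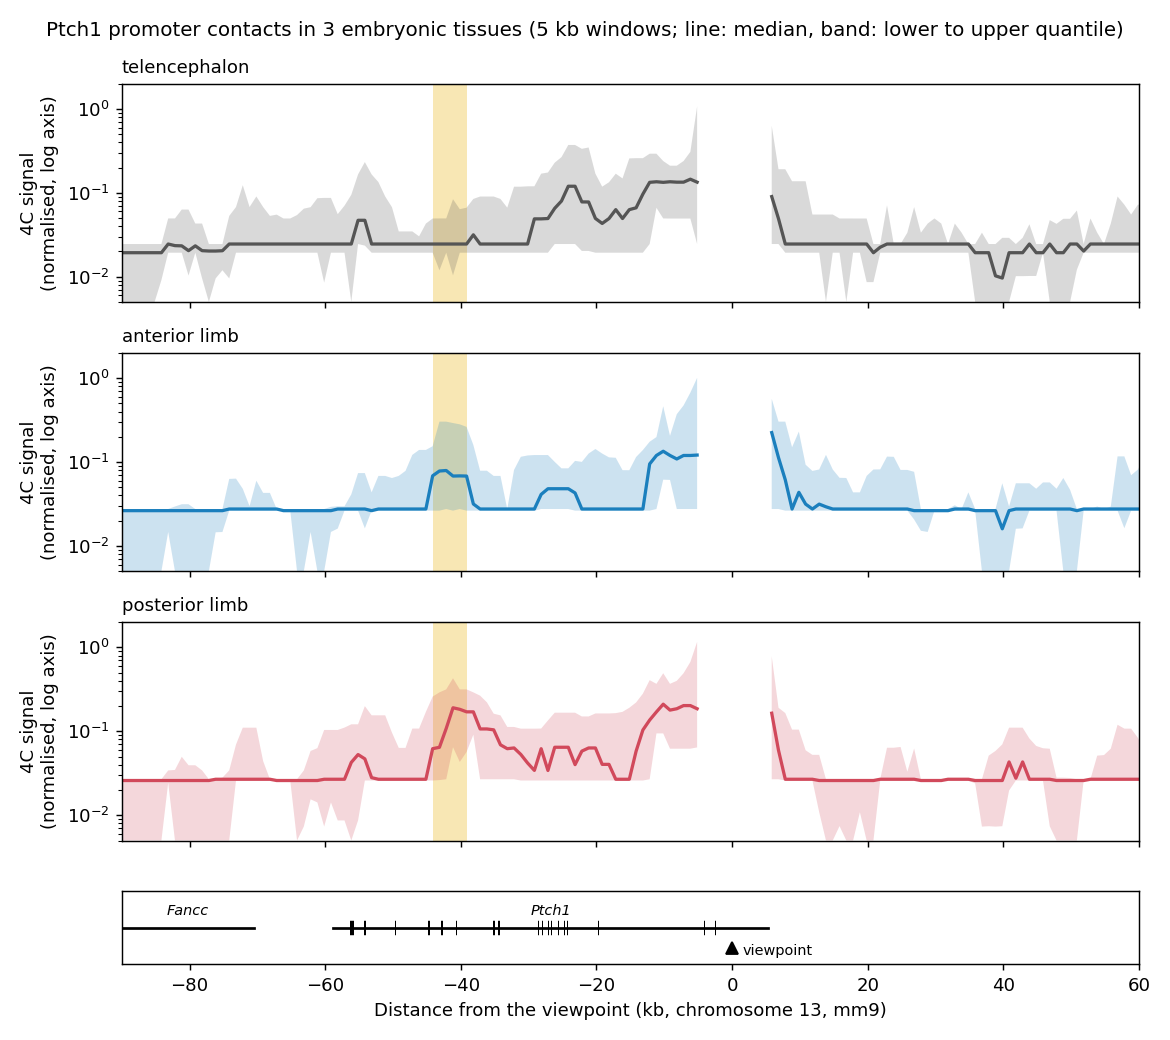
4C signal of the Ptch1 promoter (log axis, normalised units) against distance from the viewpoint in kb for telencephalon, anterior limb and posterior limb; lines are 5 kb running medians, bands run from the lower to the upper quantile of the window and are clipped at 0.005, and positions within 5 kb of the viewpoint are not drawn. The yellow bar marks 44.2 to 39.2 kb along the Ptch1 body, where the mean was 0.0245 in telencephalon, 0.0718 in anterior limb and 0.130 in posterior limb; ticks on the gene are exons of the transcript with 23 exons.

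Limb and telencephalon differed inside the Ptch1 gene. Both limb libraries contacted 1 interval at least 2 times as strongly as telencephalon, at 63,624,984 to 63,629,984, 44.2 to 39.2 kb from the viewpoint. It spans exons 16 and 17 and the introns around them, and 6.54% of it is exonic. Positions were treated as window centres, so the fragments behind an interval reach 2.5 kb beyond each end. Exon and intron names here and below therefore describe positions and are finer than the windows. Mean signal there was 0.0245 in telencephalon, which is that library's second repeated level, 0.0718 in anterior limb and 0.130 in posterior limb. Anterior limb was thus 2.93-fold and posterior limb 5.30-fold above telencephalon, or 2.15-fold and 3.95-fold after each profile was divided by its median. Telencephalon was at this level at all 6 positions, so the folds are relative to a level whose origin, measured or filled in, is not given in the sources used here. It was not the lowest value the signal took, since the lower quantile of telencephalon averaged 0.0166 in these windows.

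Folds at the 6 overlapping positions of this Ptch1 interval were 2.54 to 3.24 for the limb library nearer to telencephalon. At 5 of the 6 positions the running median of both limb libraries exceeded the upper quantile of telencephalon. The mean upper quantile was 0.0604 in telencephalon, 0.266 in anterior limb and 0.322 in posterior limb. The limb parts themselves differed there by 1.81-fold. The windows held 34 to 46 unique fragment ends. The excess of anterior limb was narrow: the fold was 4.02 in 2 kb windows, stayed at 2 or more up to 10 kb, and was 1.12 from 15 kb upward, which is the ratio of the repeated levels, whereas posterior limb was at least 2 times telencephalon at 40 of 48 widths. With posterior limb alone, 2 intervals passed, and the further one lay upstream of Ptch1 at 63,707,984 to 63,711,984 with a fold of 2.10, a position named after its values were seen. This fold is as deposited, and the posterior median was 1.34-fold above that of telencephalon. At 10 to 50 kb on the upstream side telencephalon was nowhere above 0.0245, its second repeated level.

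Telencephalon exceeded both limb libraries in 1 interval nearer the promoter, at 63,651,984 to 63,653,984, 17.2 to 15.2 kb away in intron 2 of Ptch1. Its mean was 0.0584 there, against 0.0276 in anterior limb and 0.0269 in posterior limb, a fold of 2.10 as deposited and 2.89 after division by the medians. Both limb libraries were at their second repeated level at all 3 positions. The folds are therefore relative to levels whose origin, measured or filled in, is not given in the sources used here. Of the 3 positions of this interval 2 passed, the lowest fold was 1.79, and telencephalon exceeded the limb upper quantiles at 0. The mean upper quantiles there were 0.192 in telencephalon, 0.0909 in anterior limb and 0.176 in posterior limb. The strongest telencephalon contact beyond 10 kb that met the peak rule was at 63,644,984, over exon 6 and 24.2 kb away. There its signal of 0.120 was 2.49 times anterior limb and 1.85 times posterior limb, and 3.40 and 2.49 times with that scaling. After division by the medians 2 intervals favoured telencephalon, the further one being 63,644,984 to 63,645,984 at this summit with a fold of 3.05 (named after its values were seen), and 2 did so against anterior limb alone. The intron 2 difference from posterior limb was lost in wider windows, where posterior limb was 0.866 times telencephalon at 10 kb and 1.48 times at 48 kb. Anterior limb was 0.471 times telencephalon at 10 kb and 0.910 times at 48 kb. At this distance a 48 kb window spans the viewpoint, so ratios at that width include the signal near it that the main setting leaves out.

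**Figure D2:**
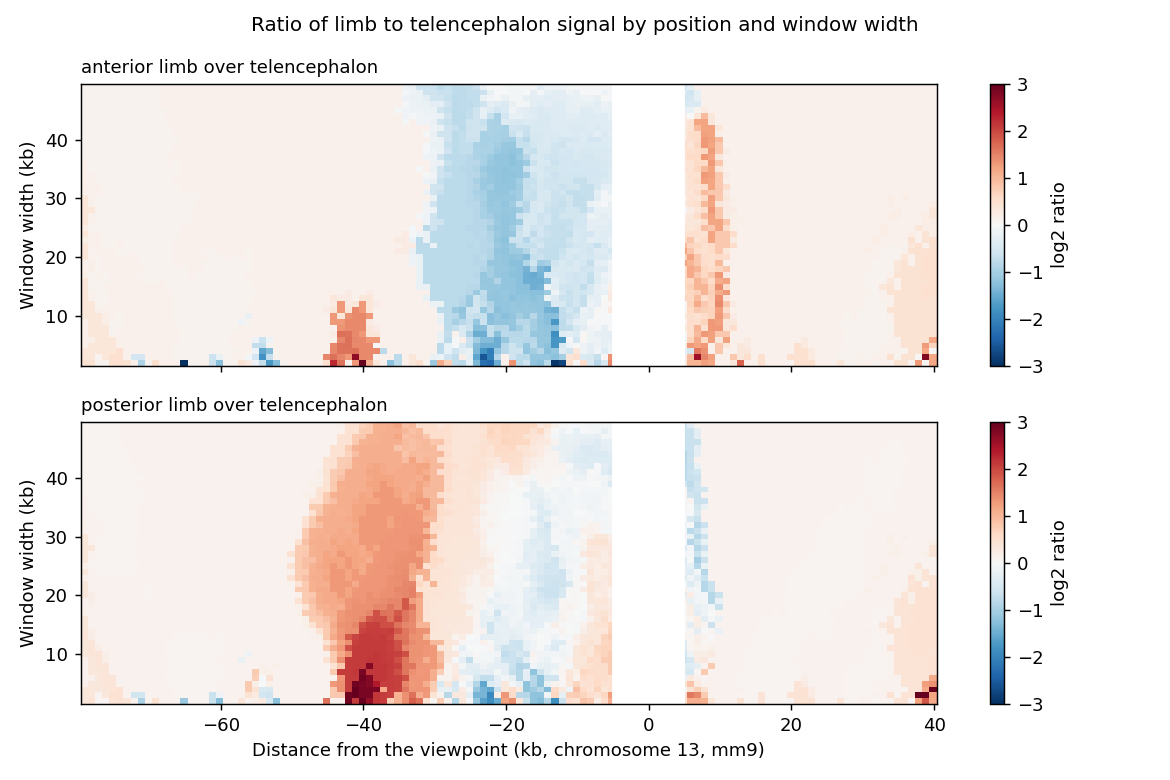
Log2 ratio of anterior limb (upper panel) and posterior limb (lower panel) to telencephalon 4C signal, by distance from the viewpoint in kb (horizontal axis) and width of the running-median window in kb (vertical axis), after adding 0.001; red is higher in limb, blue higher in telencephalon, and positions within 5 kb of the viewpoint are blank. Red at 44.2 to 39.2 kb in both panels is the limb interval, narrow in anterior limb and wider in posterior limb; pale tones elsewhere are positions where the libraries sit on their unequal repeated levels.

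Within the forelimb, the posterior part contacted stretches of the Ptch1 body more strongly than the anterior part. Posterior limb was at least 2 times anterior limb in 3 intervals, all inside Ptch1 with the main setting. In 2 kb windows and with the upper quantile, intervals outside Ptch1 were also called. The longest of the 3, 63,627,984 to 63,636,984, lies 41.2 to 32.2 kb away over exons 13 to 16, and its mean was 0.123 in posterior limb against 0.0402 in anterior limb and 0.0252 in telencephalon. That is a fold of 3.04, with 2.25 to 5.39 at its 10 positions. At 6 of these the posterior running median exceeded the anterior upper quantile. Anterior limb fell to its second repeated level, 0.0276, within this interval, so the folds are partly relative to that level. The other intervals were at 63,654,984 to 63,655,984 in intron 2 (0.0809 against 0.0276) and at 63,646,984 to 63,648,984 in intron 3 (0.0616 against 0.0276), and there telencephalon, at 0.0814 and 0.0684, stood with posterior limb while anterior limb was at its second repeated level. These had less support: the posterior running median exceeded the anterior upper quantile at 0 positions in both, and in 2 kb windows the fold was 1.55 in intron 2 and 1.51 in intron 3. Over the 48 widths the fold was 2 or more at 8 in intron 2, with a lowest of 1.07, and at 27 in intron 3, with a lowest of 1.42. Wider windows there reach within 10 kb of the viewpoint, which the main rule leaves out, so these counts partly follow distance. The mean upper quantiles were 0.251 against 0.127 in intron 2 and 0.155 against 0.123 in intron 3.

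Anterior limb was above posterior limb in 0 intervals with 5 kb windows. In 2 kb windows there was 1, named after its values were seen, at 63,624,984 to 63,625,984 with a fold of 3.68, at the far end of the interval in which both limb libraries exceeded telencephalon. With the upper quantile, an alternative chosen after seeing the data, 5 intervals favoured anterior limb and 11 favoured posterior limb, or 4 and 5 when the offset was also changed, to the smallest upper quantile above 0 (0.0234). For the interval over exons 13 to 16 the fold was 1.85 to 3.24 over the 48 window widths and 2 or more at 39 of them, and it was 1.97 in 2 kb windows and 1.70 with the upper quantile (1.60 with its own offset).

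**Figure D3:**
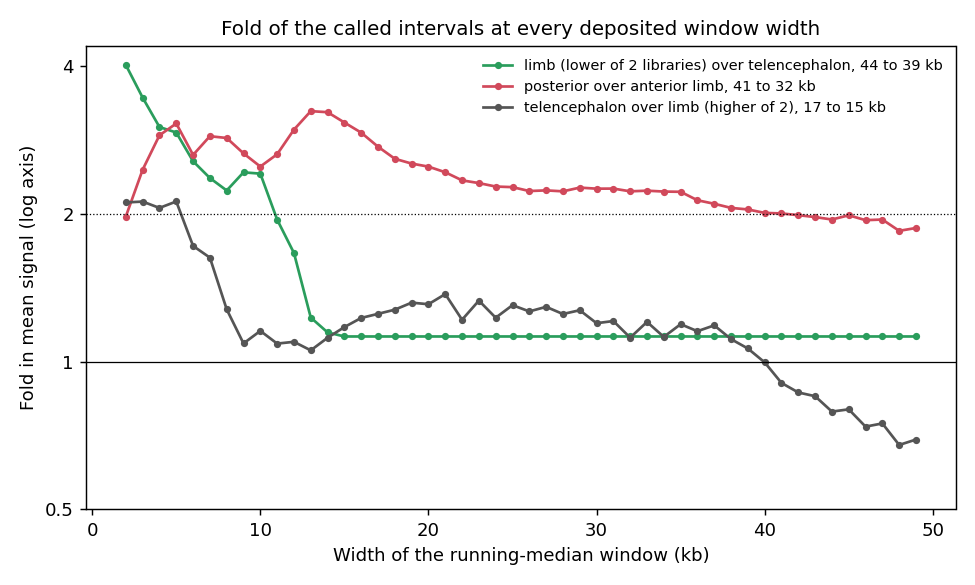
Fold in mean 4C signal (log axis) against the width of the running-median window in kb for the interval higher in limb (44.2 to 39.2 kb, limb library nearer to telencephalon), the longest interval higher in posterior than anterior limb (41.2 to 32.2 kb) and the interval higher in telencephalon (17.2 to 15.2 kb); each point is 1 of the 48 deposited widths. The limb fold ran from 4.02 to 1.12, the posterior over anterior fold from 3.24 to 1.85, and the telencephalon fold, against the higher limb library, from 2.12 to 0.676, with posterior limb above telencephalon at the widest windows, which at that distance span the viewpoint.

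Contact peaks numbered 2 in telencephalon, 2 in anterior limb and 4 in posterior limb. In the limb parts they included neighbouring summits in intron 16 of Ptch1, at 63,626,984 in anterior limb (0.0793) and 63,627,984 in posterior limb (0.191), where telencephalon was at 0.0245. Posterior limb had a further peak in intron 22 of Ptch1 at 63,613,984 (0.0529, against 0.0470 in telencephalon and 0.0276 in anterior limb). This summit was 2.04 times its bin median, and the upper quantile there was higher in telencephalon, at 0.166, than in posterior limb, at 0.121. Another posterior peak lay in the intergenic stretch toward Ercc6l2 at 63,820,984, 152 kb from the viewpoint (0.0589, against 0.0193 in telencephalon and 0.0264 in anterior limb). All 3 tissues had a summit inside the annotated span of Fancc, at 63,538,984 in telencephalon (0.0495) and at 63,543,984 in anterior limb (0.0815) and posterior limb (0.0628), 130.2 and 125.2 kb away. These summits lie between the annotated Fancc starts at 63,598,586 and 63,533,053. The Fancc summits rest on windows with 8 and 2 unique fragment ends, against 30 to 42 at the other peaks, and with windows of at least 20 unique ends, a setting chosen after seeing the data, the peaks numbered 1, 1 and 3.

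The most upstream annotated starts of the neighbouring genes were at baseline in the running median. Other Fancc transcripts, among them those that reach the lower end of the gene, start at 63,533,053, where no value was read. At the most upstream Fancc start, 70.6 kb from the viewpoint, the running median was 0.0245 in telencephalon, 0.0276 in anterior limb and 0.0269 in posterior limb, and the same values were found at the Ercc6l2 start, 247 kb away. The upper quantile was higher at both, with 0.0904, 0.0600 and 0.111 at Fancc and 0.0903, 0.0435 and 0.121 at Ercc6l2. At the start of Hsd17b3, a steroid dehydrogenase gene 521 kb away, the upper quantile was 0.0245, 0.0276 and 0.0269.

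Across the 780 positions the profiles correlated with a Pearson r of 0.849 for telencephalon and anterior limb, 0.746 for telencephalon and posterior limb, and 0.806 for the limb parts. Spearman's rho was 0.674, 0.610 and 0.599. After the trend with distance was removed, rho was 0.466 and 0.431 for telencephalon with anterior and posterior limb and 0.788 for the limb parts, while r was 0.824, 0.678 and 0.770. The trend was the mean of the 3 profiles in each bin and side, and the same trend was taken from every profile. With most positions on repeated levels, rho without trend can follow these shared bin means. It therefore does not show which tissues are most alike. All these correlations are across overlapping windows, and the detrended r fell to 0.0118 for telencephalon and anterior limb in 10 kb windows and changed sign to -0.381 for the limb parts in 20 kb windows. It was 0.654, 0.242 and 0.341 over windows with at least 20 unique ends, a setting chosen after seeing the data, which leaves out, among others, 4 positions in Fancc that were at 0 in all 3 libraries.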

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

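The tests in this part, and the positions named only here, were chosen after the results were seen. The upper quantile is a column that the comparisons use only beside the running median or as an alternative. In it posterior limb stood at least 4 times above telencephalon, the control tissue, and above its own median of that column, in 5 stretches. They lie outside the interval described above, all in windows with at least 20 unique ends, and anterior limb had none. All 5 are intergenic and on the higher-coordinate side. At 63,818,984 to 63,822,984, around the posterior peak 152 kb away, the posterior upper quantile was 0.176 against 0.0263 in telencephalon, a ratio of 6.68, with 0.0422 in anterior limb. At 64,052,984 to 64,053,984 the ratio was 6.60, with 0.162 against 0.0245, and anterior limb was at 0.0714. At 64,069,984 to 64,071,984 it was 6.33, at 64,078,984 to 64,079,984 it was 4.68, and at 64,102,984 to 64,104,984 it was 7.81, with anterior limb at 0.0395, 0.0461 and 0.0276, and these 3 stretches lie beyond the 400 kb used elsewhere. In the last 4 stretches the posterior running median was 0.0269, a baseline level, and the telencephalon upper quantile was 0.0245, that library's second repeated level. These ratios are as deposited and relative to a level whose origin is not given in the sources used here. Telencephalon over limb was not screened in this way.

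The pattern weighed here is the higher posterior than anterior limb contact at 41.2 to 32.2 kb in the Ptch1 body. An offset between the baselines of the limb parts is argued against by the ratio of the posterior to the anterior median, 0.984. Folds of 2.25 or more would need an offset of that size. Both medians are themselves repeated levels, and anterior limb fell to its second one, 0.0276, within the interval. The folds are thus partly relative to a level whose origin, measured or filled in, is not given in the sources used here. A posterior library that is richer in captured fragments could contribute. An upper quantile was called raised at 2 or more times the library's median of that same column over the analysed positions. Of 600 positions lying 100 to 400 kb away, 48 were raised in posterior limb and 27 in anterior limb, a ratio of 1.78. That excess was on the higher-coordinate side, with 33 against 9, and not on the side of the interval, with 15 against 18, which leaves this explanation open. With 1 library per limb part, a difference between anterior and posterior limb cells also stays open and was not tested.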

How the results depend on the processing

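The upper quantile (with the main offset or with its own) and the windows with at least 20 unique ends were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each tissue has 1 library. Of the values that answer a comparison, 480 stayed within 1.5 times of the main value, 70 moved further and 2, both correlations, changed sign; for single intervals 26 stayed and 14 moved. Ratios can turn without moving that far: of 15 limb over telencephalon bin ratios above 1, 13 were below 1 after division by medians, 7 after division by sums and 1 in 2 kb windows, and for the scalings this follows from 1 factor per library. The count of intervals higher in limb stayed at 1 with 2 and 10 kb windows, both scalings, the pseudocount, a fold of 1.5, a run of 5 kb and anterior limb alone, but the interval covered 4 positions after division by medians and 3 in 2 kb windows, against 6. The contact levels have no value under the scalings, which change their unit, and only their ratios do. Unknown depth keeps counting error out of all these values, and apart from what a rule's own construction sets (a stricter fold, a longer run, a wider exclusion), the cause was not tested.

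Peak counts below are for telencephalon, anterior limb, posterior limb, anterior peaks shared with posterior limb, and telencephalon peaks shared with limb, with main values 2, 2, 4, 2 and 1. They were 8, 5, 8, 4 and 4 in 2 kb windows, 1, 1, 0, 0 and 0 in 10 kb windows and 0 for all in 20 kb windows. They were 1, 1, 1, 0 and 0 with a peak factor of 3, and 9, 10, 14, 8 and 6 with the upper quantile. With at least 20 unique ends they were 1, 1, 3, 1 and 0. A summit of 20 kb left 1 in telencephalon.

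Intervals higher in limb (main 1) numbered 0 in 20 kb windows, 0 at a fold of 3, 2 with posterior limb alone, and 5 with the upper quantile or 1 with its own offset. Intervals higher in telencephalon (main 1) numbered 2 in 2 kb windows, with either scaling, at a fold of 1.5 and against anterior limb alone. They numbered 0 in 10 and 20 kb windows and with 20 kb around the viewpoint left out. Their count was also 0 with the 5th percentile pseudocount, at a fold of 3 and with a run of 5 kb. With the upper quantile, under either offset, 1 was called, at 63,644,984 to 63,647,984 (named after its values were seen) and not in intron 2. Intervals higher in posterior than anterior limb (main 3) numbered 5 in 2 kb windows, 11 with the upper quantile or 5 with its own offset, 6 at a fold of 1.5, and 1 at a fold of 3, with the pseudocount or with a run of 5 kb. Those higher in anterior limb (main 0) numbered 1 in 2 kb windows and 5 with the upper quantile or 4 with its own offset.

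The bin median for anterior limb at 10 to 50 kb on the gene-body side was 0.0276 against a mean of 0.0438. For telencephalon and anterior limb, r was 0.516 in 10 kb windows, and without trend 0.0118 in 10 kb windows, 0.173 in 20 kb windows, 0.474 with the pseudocount and 0.398 with the upper quantile and its own offset, while rho without trend was 0.739 in 2 kb windows. For telencephalon and posterior limb, r without trend was 0.148, 0.370 and 0.324 in 10 kb windows, 20 kb windows and with the pseudocount, and 0.242 with at least 20 unique ends, with rho 0.731 in 2 kb windows. For the limb parts, r without trend changed sign to -0.0190 in 10 kb windows and to -0.381 in 20 kb windows, and was 0.508 with the upper quantile and its own offset and 0.341 with at least 20 unique ends, while rho was 0.502 in 20 kb windows.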

Other observations

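The tests in this part, and the positions named only here, were chosen after the results were seen. The upper quantile, which responds to a few strong fragments in a window, showed how far raised contact reached. A position was called raised when this quantile was at least 2 times that library's median of the same quantile over the analysed positions. Within Ptch1, beyond 10 kb from the viewpoint, 44 of 49 positions were raised in telencephalon, 44 in anterior limb and 49 in posterior limb. Of 192 positions in Fancc, 24, 22 and 16 were raised. The intergenic stretch from Ptch1 to Ercc6l2 had 25 raised positions in telencephalon, 38 in anterior limb and 50 in posterior limb out of 237, and the body of Ercc6l2 had 3, 0 and 2 out of 85.

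The higher limb contact at 44.2 to 39.2 kb in the Ptch1 body was set against technical explanations. After each profile was divided by its median, the lowest fold among its positions was 1.89. That value could not have come near 1, because the positions were picked for folds of at least 2. The medians differ from telencephalon by 1.36-fold in anterior and 1.34-fold in posterior limb, less than the folds. Nothing more follows on an offset between baselines. The origin of the level of 0.0245, which telencephalon held at all 6 positions with a mean lower quantile of 0.0166, stays unknown. A telencephalon library that is sparser throughout than anterior limb is argued against only in part by the other 34 positions 10 to 50 kb away on that side, where telencephalon was 1.45 times anterior limb and higher at 19 of them, compared with 0.341 times inside the interval. Leaving out positions picked for limb excess favours telencephalon. Over all 40 positions anterior limb was 0.847 times telencephalon on the mean, but telencephalon was higher at 19 of the 40. Against posterior limb the same explanation stays open, since telencephalon was 0.834 times posterior limb at the other 34 positions and higher at 14 of them, compared with 0.189 times inside. A single library standing apart stays open, since no tissue has another library and the 1.81-fold between the limb parts comes from an interval picked for their common excess, so that limb-specific looping of this part of Ptch1 to its promoter remains a hypothesis that may or may not hold in further embryos.

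For the Fancc summits at 125.2 to 130.2 kb, few usable fragment ends beside a repeat may account for the signal. Their 5 kb windows held at most 8 unique fragment ends, below the 5th percentile of 26, and the 4 positions between them, 63,539,984 to 63,542,984, had a signal of 0 in all 3 tissues and at most 4 unique ends. The upper quantile at 63,543,984 was 0.238 in telencephalon, 0.208 in anterior limb and 0.192 in posterior limb. No biological explanation was tested.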
